A study of Mus musculus with 2 samples.

How the data were processed

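The series holds 2 hybridisations of mouse genomic DNA to Agilent 2-colour arrays for comparative genomic hybridisation, 1 of adult tail DNA and 1 of whole embryos at E10.5. Each array compared offspring of a Dnmt3L+/- sire with control DNA, and the groups and dyes were taken from the labels: on the adult array the offspring are in Cy3, on the embryo array in Cy5. The deposited files give spot intensity values as Agilent Feature Extraction 9.1.1.1 wrote them, per the file headers (version 9.1 per the submitters' processing notes). Per the file headers, the processed signals were background-subtracted and spatially detrended, dim spots were given surrogate values, and each channel was scaled by linear dye normalization. The mean and background intensity columns, per the file headers, are pixel brightness before these steps. The log10 ratio column of the deposited files is Cy5 over Cy3 of the processed signals, and the log10 values of the deposited series matrix matched it to within 0.0005 on all 44050 spots, with medians of −0.0032 (adult) and 0 (embryo), so its scale and direction are settled and it was not centred again. The genome build and any pooling of DNA are not given in the sources used here. No per-sample column of the series matrix was left unused.

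Of 44050 spots, 1030 control spots were left out, and 8 (adult) and 34 (embryo) spots carrying an outlier mark were left out. The ratio of offspring over control was computed from the processed signals on the log2 scale, spots of 1 probe were averaged, and each array was centred on its median, with no loess. Saturated spots (1 and 2) were kept. Surrogate values entered 2.99% of adult and 0.186% of embryo spots in at least 1 channel. The 42404 probes carried 26680 names, of which 11095 were current symbols of the mouse assembly table (GRCm38.p6), 5621 were single synonyms of a current symbol and 9964 were not matched and kept as the files give them. That table was used for names and for a comparison of chromosomes, and none of its coordinates were used. Of 30910 placed probes that could be compared, 29543 lay on the chromosome that the table gives. Of the probes, 40521 lay on autosomes, 1569 on X and 314 on unplaced contigs, 1 of these from Y. The median spacing was 21.8 kb and probe lengths ran from 45 to 60 bases.

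For each chromosome the median was taken with a 95% interval from 2000 bootstrap draws of blocks of 20 probes, and X was set against 10000 random autosomal runs of as many consecutive probes, for which 14 chromosomes were long enough. Segments were found by least-squares optimal partition, with a penalty of 3 times the noise variance times the natural logarithm of the number of probes and at least 3 probes. The noise came from the differences of neighbouring probes (0.273 adult, 0.276 embryo). A segment was called when its median lay at least 0.3 log2 from the array median and it covered at most 90% of its chromosome. Called segments were counted again in 100 shuffles of the probe order, over all probes and, added after the X shift was seen, over autosomal probes. Segments of both arrays were shared when they had the same direction and at least 50% of the probes of the shorter. Both arrays were also fitted in limma (lmFit and eBayes against 0, adult array turned by −1) with Benjamini-Hochberg adjustment at 0.05.

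Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The steps were tested on simulated data of 40521 autosomal probes before use. Segmentation recovered all placed losses of 0.85 log2 with 10, 20 or 50 probes (25 of each, 100%), and 60% (adult noise) or 64% (embryo noise) of those with 5 probes. Shifts of −0.5 over 10 probes were recovered in 32% and 8%, and 1 and 7 false segments were called. The 2-array limma test recovered 0% of 100 probes at −0.85 and 94% of 100 at −2, with 1 false call.

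The main settings, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names each chromosome outside the range of the others by more than their SD and X, up to 10 gains and 10 losses per array by probes times absolute median, shared segments, and up to 10 higher and 10 lower genes per array with at least 2 usable probes. It also names the 5 higher and 5 lower probes past the limma threshold or, as none passed, those with the largest smaller ratio of the same sign on both arrays, and up to 4 members of each of 23 gene lists with the largest ratios, plus Dnmt3l. Pieces of X and list members are named in part, and some items are not reported here. Where a channel was not well above background, a fold is given. It is the brighter signal over the higher of the dim probe's own signal and the lowest signal among probes well above background. For the probes named it is almost the measured ratio, so it is an estimate and no limit. Usable was taken to mean well above background in both channels and without an outlier mark, a definition set after the files were seen and before gene values were. Lists were matched on the gene symbols of the files. Each list median was set against 10000 random probe sets of the same size, matched on signal within 10 bins and drawn from the same class of chromosome, as a description of these arrays.

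Alternatives were normexp with an offset of 50 on mean and background signals, loess within the array, centring on autosomal probes, leaving out dim or saturated probes, the deposited log10 ratios, the series matrix, the mean over X probes, X without multicopy families, a penalty factor of 5, at least 5 probes, a shift of 0.5, outlier spots kept, any shared probe as overlap, both ratios as Cy5 over Cy3, all probes in the correlation and eBayes with a trend. A planned adjustment for GC content was not run, as neither probe sequences nor a genome of the build in use were at hand. The correlation over probes of 60 bases alone was added after seeing the data.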

Results

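Genomic DNA of female mice was compared by array comparative genomic hybridisation, in which the DNA of a test and a control sample, each in its own dye, compete for the same probes. The series asks whether the genome of offspring is affected when the sire carries a single working copy of Dnmt3L, a cofactor of the DNA methyltransferases that set methylation in germ cells. All animals were labelled Dnmt3L+/+ females, and the arrays differed in stage. The adult array set tail DNA of adult offspring of a Dnmt3L+/- sire, in Cy3, against tail DNA of a C57BL/6 colony described as unrelated, in Cy5. The embryo array set whole-embryo DNA at E10.5, with the offspring of a Dnmt3L+/- sire in Cy5 and a control cross in Cy3. The labels name the embryos both as an F1 of FVB/NJ and C57BL/6 and as C57BL/6, so their strain is not settled here, and whether DNA of several animals was pooled is not given in the sources used here.

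There was 1 array per stage and no replicate of either, so the number of arrays limits the precision, and intervals below describe the spread over probes of 1 array. Each array held 42404 measurement probes, of which 42090 lay on chromosomes 1 to 19 or X. Probes were well above background in 97.3% (offspring) and 98.8% (control) of cases on the adult array and in 99.8% and 99.9% on the embryo array. Median background-subtracted signals were 40.8 and 56.3 for offspring and control on the adult array and 189 and 105 on the embryo array. Among 308 probes spotted 3 times, the median SD of the log2 ratio was 0.19 on the adult array and 0.065 on the embryo array. All log2 ratios are offspring over control. Coordinates are those of the deposited files, whose genome build is not given in the sources used here. Dnmt3l itself, with 2 probes, had a median log2 ratio of −0.089 on the adult array and 0.12 on the embryo array. As all animals were labelled Dnmt3L+/+, by the labels neither channel holds the altered allele. Where these probes lie relative to its altered part is not given in the sources used here.

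The X chromosome was lower in offspring of the Dnmt3L+/- sire than in control DNA on both arrays. On the adult array its median log2 ratio was −0.86 (95% block bootstrap interval −0.88 to −0.84 over 1569 probes, SD of single probes 0.50), a signal ratio of 0.552. On the embryo array it was −0.86 (−0.87 to −0.83, 1566 probes, SD 0.37), a ratio of 0.553. All 78 complete windows of 20 consecutive X probes, which leave out the last probes of the chromosome, had medians at or below −0.3 on each array, from −1.14 to −0.63 on the adult array and from −1.05 to −0.63 on the embryo array. Windows on the autosomes reached that level in 2 of 2015 cases on the adult array and in 1 of 2014 on the embryo array. On the adult array 95.3% of X probes lay below 0, on the embryo array 97.2%, and 1452 of 1566 did so on both.

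X was the lowest chromosome on both arrays and the only 1 outside the range of the others by more than their SD. The 19 autosome medians lay between 0.0014 (chromosome 19) and 0.019 (chromosome 5) on the adult array, with an SD of 0.0056, and between −0.013 (chromosome 6) and 0.028 (chromosome 11) on the embryo array, with an SD of 0.011. None of 10000 random autosomal runs of as many consecutive probes reached the X value, and the lowest run medians were −0.0082 and −0.016. Taken probe by probe, the median of the embryo minus adult differences over X was 0.036 (95% block bootstrap interval 0.0030 to 0.069). The X medians themselves were nearly equal, at −0.857 (adult) and −0.856 (embryo). The size of the X shift depended on the processing: with normexp background correction and an offset, on signals from before the detrending, surrogate values and dye normalization of the deposited files, it was −0.28 on the adult array and −0.54 on the embryo array, where the SD of autosome medians became 0.026. An offset of 50 added to both channels draws ratios toward 1 by construction, and more so on the dimmer adult array. How much of the smaller shift it makes was not tested.

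**Figure D1:**
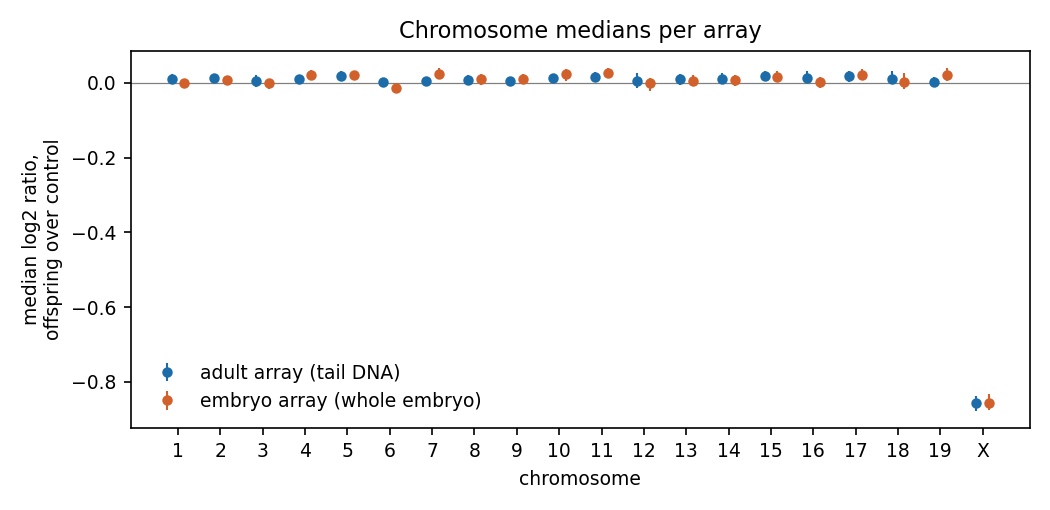
Median log2 ratio (offspring over control) of each chromosome on the adult array (blue) and the embryo array (orange), with bars for the 95% block bootstrap interval over probes. X lies at −0.86 on both arrays, and the autosomes lie between −0.013 and 0.028.

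**Figure D2:**
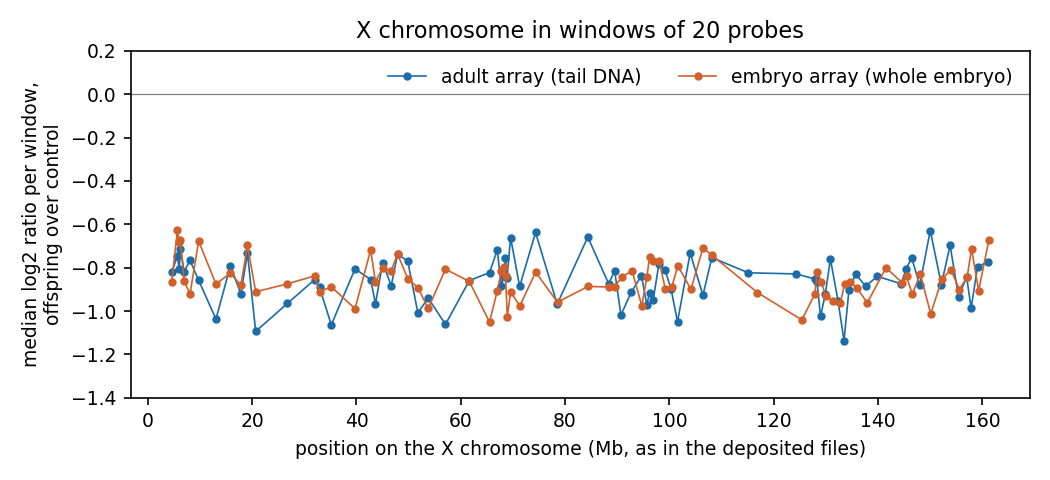
Median log2 ratio (offspring over control) of 78 windows of 20 consecutive probes along the X chromosome, by position in Mb in the coordinates of the deposited files, for the adult array (blue) and the embryo array (orange). All windows on both arrays lie below 0, between −1.14 and −0.63.

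The genes with the lowest ratios were X-linked on both arrays. Among genes with at least 2 usable probes, 333 of 340 X genes on the adult array and 381 of 391 on the embryo array had a median at or below −0.3, against 709 of 10657 and 888 of 11070 autosomal genes. All 10 lowest genes of each array lay on X. On the adult array these were Il1rapl2, of the interleukin-1 receptor family, at −1.80 (3 probes), Tmem27 (now Cltrn), which encodes collectrin, at −1.72, Cask, a scaffold protein of synapses, at −1.57, Bcorl1, Rnf128, Msn, which links actin to the cell membrane, BC023488 (now Gemin8), Rab33a, Vgll1 and Chm, at −1.48. On the embryo array they were Nsdhl, an enzyme of cholesterol synthesis, at −1.54, G630014P10Rik (now Mamld1), Mic2l1 (now Cd99l2), Rnf12 (now Rlim), a ubiquitin ligase that acts in X inactivation, at −1.51, AF199608, Tktl1, Ctps2, Fgd1, Gyk (now Gk), the glycerol kinase gene, at −1.32, and NAP066355-1, at −1.30. None of the 10 was shared between the arrays, and Il1rapl2 had −1.02 on the embryo array while Nsdhl had −0.86 on the adult array. The SD over the probes of a gene ran from 0.089 (Il1rapl2) to 1.04 (BC023488) on the adult array and from 0.045 (Gyk) to 0.44 (Mic2l1) on the embryo array. Under normexp 7 of the 40 genes named here as highest or lowest kept that place, and Il1rapl2 had −0.28 on the adult array.

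The 10 highest genes of each array were autosomal or on an unplaced contig, and none was among the 10 highest of the other array. On the adult array 1700012P16Rik had 0.99, Fbxo38, a ubiquitin ligase component, 0.92, Gcc1 0.91, TC1465779 0.87, and Srebf1, a transcription factor of lipid synthesis, 0.87, followed by Amd1, 2410004F06Rik (now Tdrd12), Exosc3, Zfp598 and Btd, at 0.81. All 10 rested on 2 probes and all 10 lay below 0 on the embryo array, between −0.47 for Amd1 and −0.044 for Btd. The probes of 1 gene often disagreed, such as 0.37 and 1.45 for Gcc1 and 0.22 and 1.52 for TC1465779, and the SD lay between 0.34 and 0.92 except for Fbxo38 (0.047). On the embryo array Gtf2h4, a subunit of transcription factor TFIIH, had 1.80, 2410104I19Rik (now Puf60) 1.61, AK015109 1.47 and Prm1, the protamine that packs sperm DNA, 1.32, followed by Tesc, Nek8, Hmgn3, Gna15, Gsn and Gdap1l1, at 1.16. Their adult values lay between −0.43 for 2410104I19Rik and 0.16 for AK015109. The SD over probes lay between 0.76 and 1.75 except for Gtf2h4 (0.11) and Prm1 (0.19), and 2410104I19Rik, AK015109 and Gsn each had a probe below 0, at −1.14, −0.46 and −0.065. The 2 Gtf2h4 probes lay between 33384046 and 33384119 and the 3 Prm1 probes between 13482660 and 13482833. Probes this close read nearly the same sequence, so their low SDs are not agreement of separate parts of a gene.

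A block of chromosome 3 was lower on both arrays, from 141049857 to 141851709 (802 kb, 21 probes). Its median log2 ratio was −0.94 on the adult array (SD over probes 0.29, ratio 0.520) and −0.88 on the embryo array (SD 0.40, ratio 0.542), and all 21 probes lay below 0 on each. The block held probes of Bmpr1b, a receptor for bone morphogenetic proteins, Nrap, Pdlim5, Gbp1 (now Gbp2b) and Gbp2, guanylate-binding proteins induced by interferon, Ccbl2 (now Kyat3), Gtf2b, the general transcription factor TFIIB, Pkn2, a protein kinase, and 9530052C20Rik. Names and places are those of the files. As the mouse assembly table gives another chromosome for some probes, a name that rests on 1 probe, such as Nrap, can be wrong. Pkn2 had −1.07 on the adult and −1.13 on the embryo array (there from probes at −1.91 and −0.35), Gtf2b −0.98 and −1.04, Pdlim5 −0.89 and −0.87, and the 6 probes of Gbp1 −0.82 and −0.81. The 30 probes to the left had medians of 0.063 and −0.13 and the 30 to the right −0.011 and −0.041. The next probe to the left, ending at 140964239, also lay in Bmpr1b, and the next to the right, of Gm1651, began at 143092985, so the right end is known less closely. The block was called in all 11 alternative settings on each array, with medians from −0.95 to −0.45 over the 7 of them that change the signal, normalization or probes, and in 0 of 100 joint shuffles of the probe order did both arrays share any segment.

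**Figure D3:**
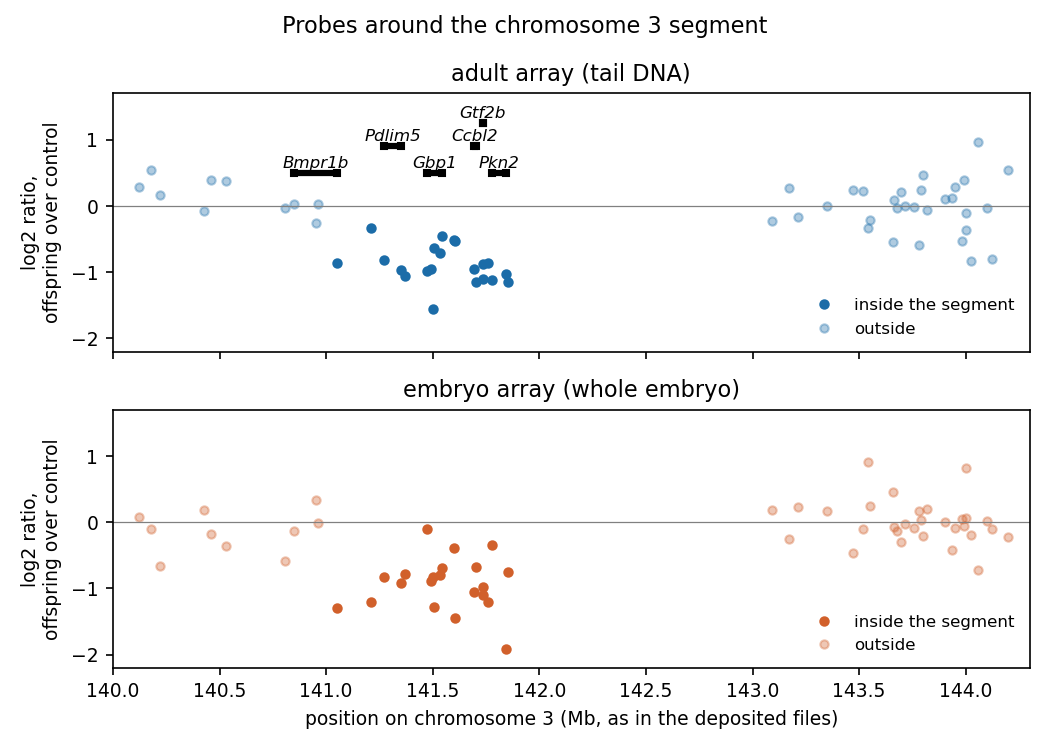
Log2 ratio (offspring over control) of single probes around the chromosome 3 block on the adult array (upper panel, blue) and the embryo array (lower panel, orange), by position in Mb in the coordinates of the deposited files. Full points are the 21 probes inside the block, all below 0 on both arrays, pale points are probes outside it, and black bars in the upper panel span the probes of 6 genes.

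Outside X and this block, few autosomal segments were called on the adult array and short gains on the embryo array. The adult array had 3 autosomal segments, all losses: the chromosome 3 block, a stretch of chromosome 4 from 87537226 to 87559678 (5 unnamed or predicted transcripts, median −0.78, embryo 0.15), and a stretch of chromosome 7 from 98931553 to 98982728 with Dub1a (now Usp17lb), a deubiquitinating enzyme gene, at −1.30 (3 probes, of which 2 were well above background, embryo 0.43). The latter pair of segments falls outside the naming rule and was chosen after the values were seen. The embryo array had 18 autosomal gains and 1 loss, the chromosome 3 block, and 13 of the 19 had 3 probes. The gain with most probes ran on chromosome 10 from 79878094 to 80020335, with Fgf22, Rnf126, Fstl3 and Palm (12 probes, 0.73, adult −0.22). Others held Accn3, Cdk5 and Slc4a2 on chromosome 5 (6 probes, 0.87, adult −0.080), Gtf2h4 and Ddr1 on chromosome 17 (3 probes, 1.72, adult 0.040), and Ncln, Gna15 and Gna11 on chromosome 10 (5 probes, 1.001, adult −0.21). Segments of 3 probes held 2410104I19Rik on chromosome 15 (1.61, adult −0.43), Pcnt2 on chromosome 10 (1.47, adult 0.17), 2500002G23Rik (now Zfp777) on chromosome 6 (1.42, adult 0.027, all within 0.209 kb), Irf3, Lrdd and Rplp2 on chromosome 7 (1.26, adult −0.30), and Amh on chromosome 10 (1.23, adult −0.31). The developmental regulators Hoxb9 to Hoxb4 on chromosome 11 had 0.45 (8 probes, adult −0.072). Among the gains named here the SD over probes ran from 0.21 (Gtf2h4 and Ddr1) to 1.33 (2410104I19Rik).

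Shuffling the order of autosomal probes within an array gave similar numbers on the adult array and fewer on the embryo array. The mean over 100 shuffles was 3.45 segments with a maximum of 8 on the adult array, against 3 called, and 6.79 with a maximum of 15 on the embryo array, against 19 called. Gains made up 6.61 of the embryo mean. The longest shuffled segments had 12 and 15 probes, and 1 autosomal segment per array, the chromosome 3 block, was longer. Over the whole genome 20 segments were called on each array, of which 17 on the adult and 1 on the embryo array were pieces of X, and shuffles of all probes gave means of 16.08 and 10.62 with maxima of 23 and 18. Such shuffles scatter the low X probes over all chromosomes, so their counts are not those of probe noise alone and do not bear on the X pieces. Of the X pieces on the adult array, 14 were losses, the longest of 343 probes at −0.85, and 3 were gains of 3 probes each, of which at most 2 were well above background in both channels, while the piece on the embryo array ran from 3777634 to 6481912 (87 probes, −0.67). The counts depended on the settings: 2 adult segments without dim probes, both autosomal, 1 adult and 3 embryo segments with a penalty factor of 5, 4 embryo segments under normexp and 10 with at least 5 probes. As segments over more than 90% of a chromosome were not called, a count without pieces of X does not mean that X was unshifted. Without dim probes the X median of the adult array was −0.86.

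Segments shared by both arrays in the same direction numbered 3 when counted as pairs, the chromosome 3 block and pieces of X near its start. The X pieces held Mycs and Nudt11 (7 probes, −0.46 on the adult array) and Bmp15, Foxp3 and Gata1 (80 probes). On the embryo array both of these pieces lay in 1 called segment (87 probes, −0.67). By the calling rule, a segment that covered more than 90% of its chromosome was not called. Called and shared pieces of X therefore do not show how far its shift extended. All 78 windows of X had medians at or below −0.3 on each array. With both ratios taken as Cy5 over Cy3 the arrays shared 0 segments, and under normexp, or without dim probes, they shared 1. Across autosomal probes the arrays ran in opposite directions: their log2 ratios correlated at −0.252 (Pearson, 95% block bootstrap interval −0.264 to −0.240, Spearman −0.310, 40482 probes, which are not independent replicates), and 39.0% had the same sign. With X included the correlation was −0.0043, and under normexp it was −0.556 over autosomal probes.

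With both arrays as replicates of offspring over control, limma found 0 of 42362 probes at an adjusted p under 0.05 (Benjamini-Hochberg, 2-sided), and 1922 had an unadjusted p under 0.05. The smallest adjusted p was 0.217. Under normexp 39 probes passed, 16 higher and 23 lower, and 22 of the lower ones lay on X. In simulated data the same test found 0% of 100 probes lowered by 0.85 and 94% of 100 lowered by 2 on the log2 scale. Far fewer probes were shifted there than lie on X, and the simulated arrays were drawn independently of each other. The simulation therefore does not settle whether single X probes could pass with 2 arrays. The probes with the largest ratios of the same sign on both arrays were all on X among the lower ones. Pdzk11 (now Pdzd11) had −2.48 on the adult and −1.66 on the embryo array, TC1533927 −1.63 and −1.58, and Smc1l1 (now Smc1a), a cohesin subunit, −1.44 and −1.53. Tex11, a meiosis gene, had −1.66 on the embryo array and B430306D02Rik (now Taf1), a subunit of TFIID, −1.58. On the adult array their offspring signal was not well above background and measured 3.33-fold and 7.41-fold lower than control. Among the higher ones were Olfr798 (1.21 and 0.72), Brca2, a DNA repair gene (0.85 and 0.72), and NAP065620-1 (0.69 on both). Tm4sf15 (now Tspan15) and Il17rd had 1.30 and 0.71 on the embryo array, with adult control signals not well above background and offspring measured 2.45-fold and 1.76-fold higher there. These folds rest on dim signals and are not limits, compare processed signals of 1 array and are open to dye bias.

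X-linked genes in the lists fixed beforehand were low on both arrays. Of 20 X-linked single-copy genes 17 were measured, with medians of −0.87 on the adult array (percentile 45.3 among 10000 random sets of X probes of like size and signal) and −0.74 on the embryo array (percentile 97.8). Examples were Ddx3x, an RNA helicase, at −1.11 on the adult array, Dmd, the dystrophin gene, at −0.94 and −0.92, Atrx, a chromatin remodeller, at −0.79 and −1.07, and Zfx at −0.17 and −1.12. Mid1, which spans the boundary of the pseudoautosomal region, was the 1 gene of 4 measured in its list and had −1.02 and −0.90. The 5 DNA methyltransferase genes had −0.045 (percentile 20.8 among random autosomal sets) and 0.069 (percentile 80.7), with Dnmt3a at −0.11 and 0.15 and Dnmt1 at −0.014 and −0.11. Of 53 imprinted genes 44 were measured, with medians of 0.051 (percentile 90.4) and 0.054 (percentile 90.7). Among them were Peg3 at 0.59 and −0.089, Igf2r at 0.43 and 0.086, Igf2, a fetal growth factor, at 0.016 and 0.68, and, with 1 probe each, Phlda2 at −0.046 and 2.18, Dio3 at 0.59 and −0.52, Cdkn1c at 0.36 and −0.61 and Mkrn3 at 0.36 and 0.035. On the adult array 7 imprinted genes lay at least 0.3 above 0 and 0 as far below, on the embryo array 5 and 8. The 13 autosomal germline and meiosis genes had 0.029 and 0.026, with Piwil1 (1 probe) at 0.52 and 0.24, Hormad1 at −0.49 and 0.062 and Ddx4 at 0.029 and −0.63, and Tex11 on X had −1.27 on the embryo array, while on the adult array 1 of its 2 probes was well above background in both channels, at −2.48. Under normexp Tex11 had −0.21 (both probes, adult) and −0.58 (embryo).

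The 10 autosomal genes known to vary in copy number between mouse strains had medians of 0.084 and −0.063, with Entpd4 at −0.27 and 0.33 and Wdfy1 at 0.061 and −0.49, and Nnt, on an unplaced contig, had −0.045 and 0.22. Of the 9 Y-linked genes Uty alone was measured, by a probe that the files place on an autosome, at −0.37 and 0.34. Among multicopy families, 592 autosomal odorant receptor genes had medians of −0.027 (percentile 0.15) and 0.0066 (percentile 10.1), while 4 on X had −0.85 and −1.14. Medians were −0.017 and −0.016 for 55 vomeronasal receptors, −0.049 and −0.049 for 25 defensins, 0.033 and 0.036 for 60 cytochrome P450 genes, −0.083 and 0.0029 for 16 H2 histocompatibility genes, −0.023 and 0.041 for 9 Nlrp genes, −0.13 and −0.012 for 4 UDP-glucuronosyltransferases, and −0.042 and 0.088 for 4 Ly49 receptors. Medians were 0.20 and 0.10 for 2 Speer genes, −0.10 and 0.042 for 3 genes matched as rearranging receptor loci, of which Tradd is matched by its name alone, 0.084 and −0.19 for Mup3, 0.49 (1 probe, percentile 99.5) and −0.00084 for Ear11 and, on an unplaced contig, −0.026 and 0.22 for Amy1. The 2 Xlr genes on X had −0.70 and −0.59, and a probe of Xlr on an autosome 0.0053 and −0.45. No Skint or Rhox gene was matched by the symbols of the files. Under normexp the adult medians of genes on X were −0.21 for the single-copy list, −0.48 for Mid1, −0.48 for odorant receptors and −0.26 for Xlr. Medians changed sign under normexp for the strain-variable genes and defensins on both arrays, for vomeronasal receptors and UDP-glucuronosyltransferases on the adult array, and for germline genes, Ly49 receptors and Ear11 on the embryo array. Under loess they did so for the autosomal Xlr probe on the adult array and for odorant and vomeronasal receptors, rearranging loci and H2 genes on the embryo array.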

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

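Of the tests below, those of probe length for the correlation and of joint shuffles for the chromosome 3 block were written down before their results were seen, and the tests of dye, background correction, male DNA, signal groups, the sire and the colony were chosen after. The bound for the background correction was set anew after normexp had given an X median above the −0.3 first asked of every alternative.

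X probes were lower in offspring on both arrays, at −0.86 and −0.86. A dye effect would keep its sign as Cy5 over Cy3, whereas X had 0.86 on the adult and −0.86 on the embryo array, and background correction and normalization as the whole cause are argued against by the value nearest 0 over the alternatives, −0.28 (adult array, normexp), since X lay at least 19.9 SDs of the autosome medians below the lowest autosome throughout, although the shift was smaller under normexp. Male DNA in the offspring channel stays open, because genes with a Y partner such as Usp9x and Eif2s3x lay at percentile 70.1 of random X probe sets on the adult array and percentile 54.8 on the embryo array, between the bounds set for a decision, and their probes can be unique to the X copy. One X copy fewer in the offspring, tied to the sire, may also account for the shift: 92.7% of X probes lay below 0 on both arrays, but a ratio does not say which DNA differs, and sire genotype cannot be told apart from colony or cross with 1 control per array.

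Autosomal probes correlated at −0.252 between the arrays. Noise of dim probes is argued against, since the correlation was −0.375 in the brightest of 4 equal groups of probes and −0.212 in the dimmest. A probe-specific dye effect is a candidate explanation: as Cy5 over Cy3, both arrays correlated with probe length in the same direction (Spearman −0.107 adult, −0.0995 embryo). Windows of 20 neighbouring probes correlated at −0.157 between arrays when oriented to offspring over control. A negative correlation of single probes carries over to medians of the same values, so the windows add no separate support. Length alone is a small part of the negative correlation, as the probes of 60 bases gave −0.246. No biological explanation was tested for this pattern.

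The chromosome 3 block with Bmpr1b, Gbp1 and Pkn2 was lower on both arrays. Dye bias is argued against by medians of 0.94 (adult) and −0.88 (embryo) as Cy5 over Cy3, and probe noise by 0 of 100 joint shuffles that gave a shared segment of as many probes. A copy number variant that segregates in the mouse colonies, unrelated to the sire, could give the same picture, as could a variant carried by the sires: 21 of 21 probes were below 0 on both arrays, and no array of control against control was analysed here, so these cannot be told apart.

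For 10 segments called on 1 array, the other array had a median of opposite sign at least 0.3 from 0, a difference that was not tested. As the dyes were swapped between the arrays, each such pair had the same sign as Cy5 over Cy3, as a dye effect would also give. On the adult array the chromosome 7 stretch with Dub1a had −1.30 (embryo 0.43). Short X stretches had 0.36 from 112759882 (embryo −0.94), 0.50 with Amot (embryo −0.71) and 0.38 with AK028243 (embryo −1.01), with 1, 2 and 1 of their 3 probes well above background in both adult channels. Embryo gains with opposite adult values were 0.99 on chromosome 3 from 28223242 (adult −0.42), 0.67 with Eef2k (adult −0.39), 1.26 with Irf3 (adult −0.30), 1.23 with Amh (adult −0.31), 1.61 with 2410104I19Rik (adult −0.43) and 1.19 with B230399E16Rik (adult −0.46).

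Some genes on unplaced contigs, which entered no chromosome or segment, had all probes at least 0.3 above 0 on 1 array. Prm1 had 1.32 on the embryo array (adult −0.030, 3 probes close together), C130022P09Rik 0.47 (adult 0.056) and Mrg2 0.44 (adult 0.13), while Zfp295 had 0.56 on the adult array (embryo −0.085). In the other direction Bicd1 had −0.51 on the embryo array, with all probes at least 0.3 below 0 (adult 0.33). Tfpt, at 0.59 on the embryo array, and D7Ertd458e, at −0.45 on the adult array, had probes that disagreed, from 0.0030 to 0.60 and from −1.05 to 0.14.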

How the results depend on the processing

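All alternatives were fixed before the data were examined except the correlation over probes of 60 bases alone, and none reversed a called result, although medians of some gene lists changed sign. Of the values that answer a comparison, 63 stayed as reported, 20 moved and 1 newly passed its threshold, and for single genes and lists 122 stayed and 50 moved. Some could hardly move. Centring on autosomal probes leaves the SD of autosome medians and the correlation unchanged by arithmetic. The series matrix repeats the deposited log10 ratios, and saturated spots numbered 1 (adult) and 2 (embryo). The tally is therefore no measure of robustness. Staying meant lying within the interval or spread of the reported value or, for counts, within a set ratio of it. For the adult SD of autosome medians the interval was widened down to the reported value, which lay below it. Where no construction shows it, the cause was not tested. The normexp offset of 50, added to both channels, draws ratios toward 1 by construction, and more so for dim signals. Its share in the normexp changes below was not tested. Under normexp X was −0.28 (adult) and −0.54 (embryo), the SD of autosome medians 0.026 (embryo), segments 4 (embryo), shared segments 1, the correlation −0.556, probes past the limma threshold 39, and 7 of 40 named genes kept their place. X was −0.82 (embryo) under loess, with an SD of 0.0084, and −0.83 (adult) with either the uncentred log10 ratios or the series matrix. Without dim probes the SD was 0.0050 (adult), segments 2 (adult), shared segments 1 and the correlation −0.266. The X median stayed at −0.86 on both arrays there, and segments over more than 90% of a chromosome were not called. A penalty factor of 5 left 1 (adult) and 3 (embryo) segments, and a minimum of 5 probes left 10 (embryo), by construction. As Cy5 over Cy3 the arrays shared 0 segments, and with X included the correlation was −0.0043. The GC alternative was not run. Adult signals near background limit ratios there, with 97.3% of offspring probes well above it. No paired analysis was possible because each stage has 1 array and the labels give no replicate numbers.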

Other observations

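The regions, probes and genes described here were chosen after their values were seen. Apart from the tests that used the X genes with a Y partner or the chromosome 3 block, no explanation of them was tested. Of the 5 lowest same-sign probes, 4 lay close together on X, TC1533927 at 95095655, Pdzk11 at 95225926, Tex11 at 95615031 and B430306D02Rik (now Taf1), a subunit of the general transcription machinery, at 96165013. On the adult array an X segment from 95392442 to 95615090 with Dlgh3 and Tex11 had a median of −1.54 (5 probes, of which 3 were well above background), and the same probes had −0.996 on the embryo array.

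Some X probes lay near 0. Of 1376 X probes well above background in all channels, 77 on the adult and 81 on the embryo array lay above −0.3, and 9 did so on both, where independent lists would share 4.53. Among them were probes of Ppp1r3f, Gpkow, Gm8 (now Slc25a43), 4930432H15Rik, Xlr3b, of a multicopy family, Plxna3, Jarid1c (now Kdm5c), a histone demethylase, and NAP061281-1. Jarid1c had 1 probe at −0.15 and −0.13 and another at −0.70 and −1.03. The 7 X genes with a Y partner, Usp9x, Ddx3x, Utx (now Kdm6a), Ube1x (now Uba1), Zfx, Eif2s3x and Jarid1c, had medians of −0.80 on the adult and −0.86 on the embryo array over 14 probes, and without Jarid1c they lay at percentiles 42.6 and 53.7 of random X probe sets.

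Outside X, the lowest autosomal genes with at least 2 usable probes included members of the chromosome 3 block on both arrays, Pkn2, Ccbl2 and Gtf2b on the adult array and Pkn2, Gtf2b, Gbp2, Pdlim5 and Ccbl2 on the embryo array. Others stood low on 1 array alone, such as F730047E07Rik (now Mms22l), a DNA repair gene, at −0.99 on the adult array (3 probes, from −1.03 to −0.022) and −0.012 on the embryo array, and Mapk6, a protein kinase, at −0.92 on the embryo array (2 probes, −1.41 and −0.44) and 0.44 on the adult array. The 5 lowest same-sign autosomal probes belonged to Pkn2, Gtf2b, Ccbl2, Pdlim5 and Gbp1, all in that block. The 1 probe from a Y contig, of Rbm31y, was not well above background in any channel of either array.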
